A study of Arabidopsis thaliana with 12 samples.

How the data were processed

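Leaf RNA of Arabidopsis thaliana was measured in 12 libraries, 3 each of the Columbia wild type and of lines labelled anac017, anac082 and anac090, which by their labels carry T-DNA insertions in NAC transcription factor genes. All leaves were 18 days old. Per the labels' protocols, poly(A) RNA was made into strand-specific libraries with a TruSeq kit and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, TopHat, Cufflinks and the genome build TAIR10, with no role or order given, and how the values were scaled is not given in the sources used here. The groups and replicate numbers come from the sample titles. Nothing in the labels says that the 3 libraries of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

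The deposited table has 33726 entries and holds log2 values, by their range and distribution: no value is below 0, and 2 to the power of the value minus 1 sums to nearly the same total in each library. The values were treated as log2(abundance + 1). The sorted values of the 12 libraries differ by at most 0.08 log2 units at the same rank, so the libraries had been quantile normalized between each other before they were deposited. This step fixes the distribution of each library: a change in total RNA, or a rise of most genes together, is not visible in such values. No read counts are kept and whole reads could not be recovered, so the depth of each library is unknown and no interval or detection floor that needs it is given. In wild type replicate 1, the 2030 lowest values above 0 fell as gene length rose (Spearman correlation across genes -0.24). An exact 0 may be a failed estimate, and a gene at 0 is described as listed at 0. A total of 529 entries (1.57%) have no gene identifier and were kept out of the tests of genes. Start positions in the table count from 0 and are given here counted from 1, on the TAIR10 coordinates of the table. Gene symbols come from the table and, where it gives none, from the gene table of the TAIR10.1 assembly, in which 32454 identifiers were found and from which no coordinates were taken.

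Genes with a mean back-transformed value of at least 1 over the 12 libraries were tested, 16817 in all. The test was limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes with a mean-variance trend, on the deposited log2 scale, which has a pseudocount of 1 built in. Fold changes are on this scale and understate the change of genes with low values. All 12 libraries entered 1 model with 4 groups, so the comparisons share an estimate of the spread, and the adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A gene with the values of the 3 libraries of each group on separate sides is called separated, which chance gives in 10% of genes. The 3 comparisons of a mutant with wild type answer the design of the study, and in the 3 comparisons between mutants the wild type libraries enter only through the filter and the shared spread. The targeted genes were also tested by an exact permutation test, one-sided for a lower value, of the 3 libraries of the mutant against the other 9.

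A set of 26 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not said here to be added later. The lists cover salicylic acid (SA) synthesis, SA-responsive defence, transcription factors and oxidases of reactive oxygen species (ROS) and stress, ROS scavenging, the mitochondrial dysfunction response, senescence-associated genes, chlorophyll breakdown, NAC factors of stress and senescence, photosynthesis, chlorophyll synthesis, jasmonate, ethylene, abscisic acid, cytokinin type-A response regulators, heat shock, protein folding in the endoplasmic reticulum, anthocyanin, camalexin with indole glucosinolates, aliphatic glucosinolates, ribosome assembly, the circadian clock, and markers of guard cells, vasculature, epidermis, cell division and flowers. All 310 members are in the table and 269 were tested. Lists with at least 3 tested members were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes, and adjusted over the lists and the 3 comparisons with wild type together, or over the lists and the 3 comparisons between mutants. Camera with a correlation estimated from the residuals and limma's fry were run beside it. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

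Named genes are the 3 targeted genes, the 8 genes with the largest rise and the 8 with the largest fall in each comparison with wild type (5 each between mutants), and up to 4 members with the smallest p of each list that passed and of each SA, ROS, mitochondrial, senescence and NAC list. The largest changes were taken among genes past the threshold, separated, and in the upper part of the tested genes by mean value, above their median. In a comparison with fewer than 5 called genes all of them are named. The other called genes of anac082 against wild type, and list members outside this rule, are named because their values were seen.

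For the overlap between comparisons that share the wild type libraries, 100 simulated sets of unchanged groups were drawn. They were compared with a shared simulated wild type, drawn from the deviations of the wild type libraries. The overlap of independent lists was computed from the calls in each direction. The simulated groups were drawn from the deviations of the mutant libraries, which sum to 0 within a line, so that 2 simulated groups are not fully independent and can correlate at 1. Whether equal replicate numbers mark paired libraries was checked by the correlation across genes of the deviations from the group means. It was over 0.1 for every number in the comparisons of wild type with anac017 (0.49, 0.37 and 0.26), with anac082 (0.39, 0.24 and 0.22) and with anac090 (0.41, 0.22 and 0.16), and in anac017 with anac082 and with anac090. The pairing thus comes from the values, since no label says what a number stands for.

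The procedure was tested on simulated data with 16817 genes, in 10 runs with 200 genes changed in anac017 against wild type. The changes were planted only in genes with a wild type mean above 2 on the log2 scale, so recovery at lower values is not known. Of the genes changed 2-fold 78.4% were called, of those changed 4-fold 96.2%, and 4.82% of calls were false. Camera gave p under 0.05 for 7.08% of lists in simulated anac082 against wild type, where no change was planted. The noise was drawn independently for each gene, with the same spread in all groups and no outlying library. These shares therefore do not give the false rate for real lists, whose genes can vary together.

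Alternatives were a pseudocount of 0.1 or 10, no filter or a minimum mean of 5, rescaling by trimmed means of M values or by medians of ratios (both computed directly on the values), a repeated quantile normalization, no variance trend, weights per library, a model of only the groups compared, the replicate number as a block, leaving out each library of the groups compared, a minimum change of 2-fold and a threshold of 0.01. Leaving out a library of a group not compared, and leaving out anac082 replicate 1 and anac090 replicate 3 together, were added after the data were seen. The design had foreseen linear values: because the deposited scale is log2, no further logarithm was taken. Tests of counts were left out because they need whole reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.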

Results

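RNA was measured in leaves of Arabidopsis thaliana at 18 days of leaf age, in 4 groups of 3 libraries: the Columbia wild type and 3 lines labelled anac017, anac082 and anac090. By its label, each line carries a T-DNA insertion in the gene of a NAC transcription factor, a plant family of regulators with many members linked to stress and ageing. The series asks how networks of NAC factors bear on the timing of age-dependent cell death. The deposited values were log2 values that had been quantile normalized between libraries, so the sequencing depth is unknown. Values are given below as log2 means ± SD and log2 changes ± SE of the limma fit, with n = 3 libraries per group, and 16817 genes were tested.

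The libraries of 1 mutant were not alike. On the first principal component, which held 51.0% of the variance, the wild type libraries lay at -35.3, -35.6 and -29.7 and the anac017 libraries at 9.31, 9.97 and 21.6. Replicate 1 of anac082 lay near wild type at -27.0, against 5.7 and 3.6 for replicates 2 and 3. Replicate 3 of anac090 lay far out at 74.1, against 15.9 and -12.7 for replicates 1 and 2. The genes of the circadian clock differed as well. A clock index, the mean of the morning genes CCA1 and LHY minus that of TOC1, GI, ELF4, LUX and PRR5, was chosen after the data were seen. It was 2.55 ± 0.93 in wild type, 1.43 ± 0.91 in anac017, 1.76 ± 0.93 in anac082 and 1.46 ± 0.72 in anac090. Within every replicate number the wild type library had the highest index, and replicate 1 had a lower index than replicates 2 and 3 in every group.

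**Figure D1:**
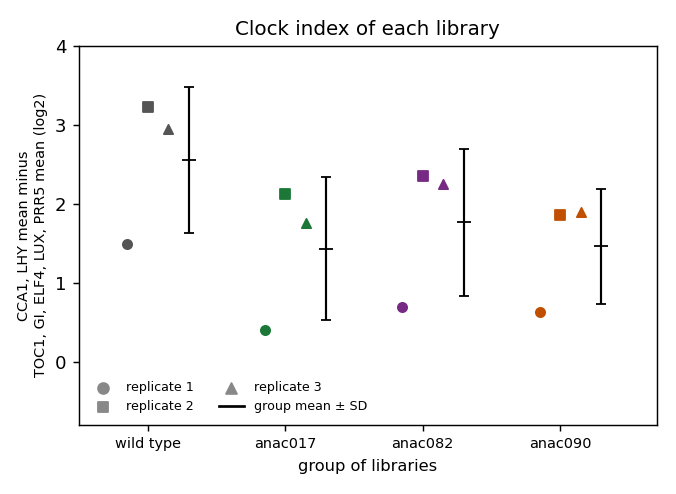
Clock index (log2) of each library by group, with the mean of CCA1 and LHY minus the mean of TOC1, GI, ELF4, LUX and PRR5; marker shapes give replicate numbers and bars the group mean ± SD (n = 3). Wild type lies at 1.5, 3.22 and 2.94 in replicates 1 to 3, above the mutant libraries of the same number.

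The transcript of the targeted gene was higher, not lower, in the libraries of both anac017 and anac082, against what their labels lead one to look for. Groups are thus named by label only, and directions are those of the labelled libraries. ANAC082 (AT5G09330, chromosome 5, 2892365 to 2895422, TAIR10) stood at 9.82 ± 0.10 in the libraries labelled anac082 and 5.02 ± 0.05 in wild type, a rise of 4.81 ± 0.11 or 28.0-fold (adjusted p = 2.7e-09). It also rose 2.06-fold in the libraries labelled anac017 (1.04 ± 0.11, adjusted p = 0.00137). Its change in anac090 was 0.36 ± 0.11 (adjusted p = 0.0647, and 0.0220 with the replicate number as a block). ANAC017 (AT1G34190, chromosome 1, 12451451 to 12454142) rose 1.81-fold in the libraries labelled anac017, from 5.89 ± 0.10 to 6.75 ± 0.08 (0.86 ± 0.14, adjusted p = 0.0152). This call was lost without wild type replicate 2 (adjusted p = 0.0716) or 3 (0.0807) and without anac017 replicate 1 (0.0592), 2 (0.0629) or 3 (0.0692), where the log2 change was 0.81 to 0.89. The lowest of these libraries lay only 0.26 above the highest other one. The adjacent gene NAC016 was at 1.14 ± 0.29 in anac017 (adjusted p = 0.0644, block 0.0183) and SERK2 at 0.46 ± 0.14 (0.0907). The median of the 4 tested genes within 10 kb was 0.32, and none passed the threshold. ANAC017 changed by 0.02 ± 0.14 in anac082 (adjusted p = 0.966) and 0.24 ± 0.14 in anac090 (adjusted p = 0.252). ANAC090 (AT5G22380, chromosome 5, 7408777 to 7410102) was the targeted gene with the lowest values, at 1.54 ± 0.20 in wild type and 0.95 ± 0.26 in anac090, a difference of -0.60 ± 0.30 (adjusted p = 0.192). It differed by 1.1 ± 0.30 in anac017 (adjusted p = 0.0751, and 0.0495 with the block) and by 0.91 ± 0.30 in anac082 (adjusted p = 0.664). In exact permutation tests of the 3 libraries of a mutant against the other 9, one-sided for a lower value, p was 0.00455 for ANAC090, the smallest the 220 splits allow, and 1 for ANAC017 and for ANAC082. For ANAC090 the other 9 include the libraries labelled anac017 and anac082, at means of 2.64 and 2.45, so this p does not compare anac090 with wild type alone. The highest anac090 library lay at 1.22 and the lowest other one at 1.35. A T-DNA insertion can leave transcript on 1 side of it, and the values do not show which part of a gene was read.

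**Figure D2:**
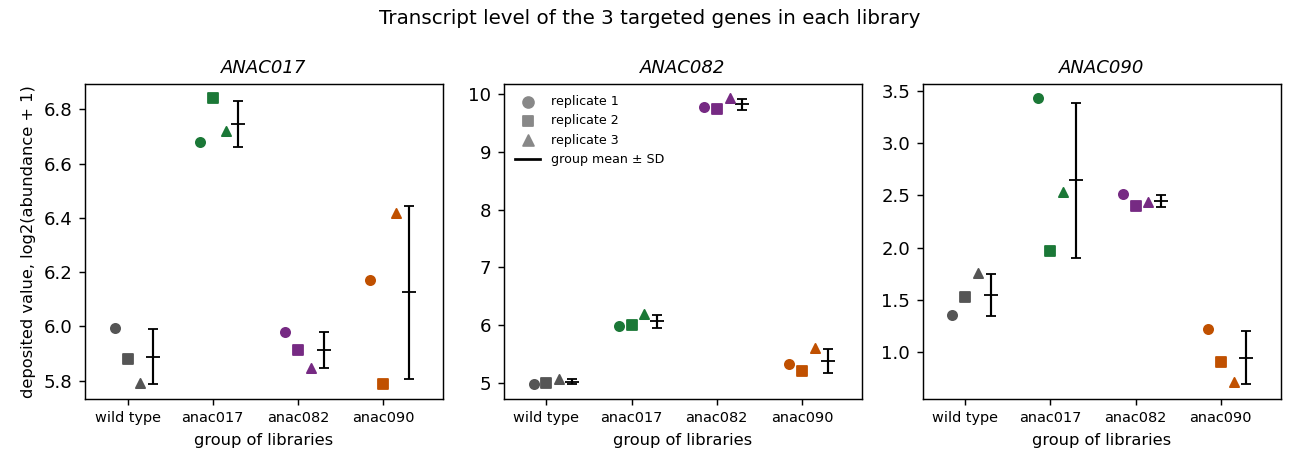
Deposited log2(abundance + 1) of ANAC017, ANAC082 and ANAC090 in each library by group; marker shapes give replicate numbers and bars the group mean ± SD (n = 3). ANAC082 lies at 9.75 to 9.94 in the libraries labelled anac082 and at 4.98 to 6.19 in the others.

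The comparison of the libraries labelled anac017 with wild type asks what differs in leaves of a line for ANAC017, known as a regulator of the response to mitochondrial dysfunction. Genes of that response were higher: UGT74E2, a glucosyltransferase of an auxin precursor, rose 3.08-fold (1.62 ± 0.27, adjusted p = 0.0196), and AT2G21640, known as UPOX, an oxidative stress marker, rose 3.45-fold (1.79 ± 0.34, adjusted p = 0.0284). The NAC factor NAC13 rose 1.75-fold (0.81 ± 0.16, adjusted p = 0.0314) and the transporter ABCB4 1.82-fold (0.87 ± 0.18, adjusted p = 0.0375). Among separated genes above the median mean value, the largest rises were those of the blue copper protein SAG14 (5.60-fold, 2.48 ± 0.45), the peroxidase PER71 (5.44-fold, 2.44 ± 0.45), CYP79B2, which makes the precursor of indole glucosinolates and camalexin (3.92-fold, 1.97 ± 0.35), and the sucrose transporter SWEET12 (3.75-fold, 1.91 ± 0.36). The glucanase BG3 (1.79 ± 0.40), the zinc finger factor ZAT7 (1.75 ± 0.39), the ubiquitin ligase ATL31 (1.68 ± 0.34) and the kinase AT1G48210 (1.5 ± 0.31) rose as well. Under the same limits, the largest falls were those of 3 small auxin-up RNA genes, SAUR15 (-1.45 ± 0.24), AT4G38860 (-1.31 ± 0.23) and AT4G38840 (-1.13 ± 0.20). The cell wall protein gene AT4G18280 (-1.12 ± 0.19), the factor BEE2 of the brassinosteroid response (-0.88 ± 0.17), the lectin gene AT5G01090 (-0.88 ± 0.13), AT1G75280 (-0.86 ± 0.19) and the sulfotransferase SOT11 (-0.85 ± 0.19) fell too. These 8 rises and 8 falls had adjusted p of 0.0127 to 0.0496. The clock index of these libraries was 1.43 ± 0.91 against 2.55 ± 0.93 in wild type.

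By list, 4 of the 14 tested genes of the mitochondrial dysfunction response rose in anac017 (9 adjusted over the list alone, 7 with the block), with a median change of 0.96. Camera gave adjusted p = 8.4e-08, and adjusted p = 0.376 with an estimated correlation. Of the 10 SA-responsive defence genes, 1 rose, the glutaredoxin GRXC9 (2.1 ± 0.39), while 10 rose adjusted over the list alone and 4 with the block. The median was 1.76 (camera adjusted p = 2.2e-06, and adjusted p = 0.450 with an estimated correlation). PR1 (2.67 ± 0.79, adjusted p = 0.0873), NIMIN-2 (2.12 ± 0.56, 0.0726) and WRKY38 (1.71 ± 0.50, 0.0833) passed with the block only (0.0352, 0.0475 and 0.0445). None of 17 SA synthesis genes passed in limma (3 adjusted over the list alone, 2 with the block), at a median of 1.14 (camera adjusted p = 1.4e-06, and adjusted p = 0.505 with an estimated correlation). The 2 were PAD4 (1.14 ± 0.28, adjusted p = 0.0606, block 0.0451) and SARD1 (1.48 ± 0.40, 0.0743, block 0.0319), both regulators of SA accumulation. Of 17 ROS and stress genes, 2 rose, ZAT12 (1.23 ± 0.27, adjusted p = 0.0454) and ZAT7 (10 adjusted over the list alone, 6 with the block), at a median of 1.03 (camera adjusted p = 1.6e-06, and adjusted p = 0.450 with an estimated correlation). Of 12 senescence-associated genes SAG14 rose (9 adjusted over the list alone, 4 with the block), with a median of 0.99 (camera adjusted p = 2.2e-05, and adjusted p = 0.376 with an estimated correlation). SAG21 (1.95 ± 0.46, adjusted p = 0.0558, block 0.0195) and GLN1;1 (1.21 ± 0.32, 0.0726, block 0.0387) were among the 4. Of 23 NAC factors none passed in limma (2 adjusted over the list alone, 2 with the block), at a median of 0.42 (camera adjusted p = 5.4e-04, and adjusted p = 0.505 with an estimated correlation). The 2 with the block were NAC016 (1.14 ± 0.29, adjusted p = 0.0644, block 0.0183) and NAC047 (1.51 ± 0.40, 0.0719, block 0.0457).

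Among the other lists in anac017, 2 of 6 camalexin and indole glucosinolate genes rose, MYB51 (1.09 ± 0.17, adjusted p = 0.0145) and CYP79B2 (4 adjusted over the list alone). Their median was 1.48 (camera adjusted p = 4.1e-04, and adjusted p = 0.450 with an estimated correlation). The 7 genes of protein folding in the endoplasmic reticulum had a median of 0.94 with none past limma's threshold, also adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.505 with an estimated correlation). BIP1 was at 0.97 ± 0.41. Lower as lists were 8 cytokinin type-A response regulators, which damp the cytokinin signal, with a median of -0.85 (camera adjusted p = 0.00246, and adjusted p = 0.473 with an estimated correlation). So were 10 aliphatic glucosinolate genes, with a median of -0.64 (6.3e-04, and adjusted p = 0.505 with an estimated correlation). No gene of either passed over all genes, and 5 and 6 were lower adjusted over the list alone. With the block ARR9 (-0.96 ± 0.22, adjusted p = 0.0525, block 0.0376), ARR6 (-1.36 ± 0.44, 0.102, block 0.0391) and ARR7 (-1.13 ± 0.37, 0.107, block 0.0376) passed. Not past camera's threshold were ROS scavenging (median 0.01, adjusted p = 0.381), chlorophyll breakdown (0.09, 0.785), photosynthesis (-0.06, 0.164), and chlorophyll synthesis (-0.34, 0.0809). The same held for jasmonate (0.10, 0.161), ethylene (0.01, mean -0.01, 0.987), abscisic acid (-0.06, 0.804), heat shock (0.18, 0.449), anthocyanin (0.33, 0.250), ribosome (0.11, 0.0605, block 0.0253) and the clock (0.07, 0.875). Nor were the markers of guard cells (-0.45, 0.128, though fry gave adjusted p = 0.0486), of vasculature (-0.02 but mean 0.30 and a test upwards, 0.449) and of epidermis (-0.27, 0.426). Of these lists SWEET12 was the only member past limma's threshold. Adjusted over the list alone, 1 chlorophyll breakdown gene was higher and 1 lower, 3 guard cell markers were lower and 2 vascular markers higher. With the block, 2 guard cell markers were lower, and 2 vascular markers, 1 jasmonate and 1 ribosome gene were higher. Also with the block, 3 clock genes were higher, PRR5 (1.01), TOC1 (0.63) and ELF4 (0.70), and CCA1 was lower (-0.80, adjusted p = 0.0943, block 0.00133). In all, 10 lists passed camera's threshold in anac017, 8 higher and 2 lower (11 with the block), 5 passed fry, and 0 passed camera with an estimated correlation, where 3 had an unadjusted p under 0.05. The lists of cell division and of floral markers had 0 tested members in any comparison.

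In anac017 a total of 248 genes rose and 103 fell (691 and 513 with the block), 74 and 28 of them at least 2-fold, and 6995 genes (41.6%) were separated, against 10% by chance. Counts of 248 and 103 became 131 and 21 without wild type replicate 1, 45 and 5 without 2, 51 and 8 without 3, 46 and 3 without anac017 replicate 1, 81 and 16 without 2, 49 and 4 without 3, 150 and 31 without anac082 replicate 3, 885 and 768 without anac090 replicate 2 and 1410 and 1547 without anac090 replicate 3, and the count of falls also moved to 50 without anac082 replicate 2 and 52 without anac090 replicate 1. With only these groups fitted 1731 rose and 1881 fell, with weights per library 2191 and 2394, at a threshold of 0.01 43 and 3, and without anac082 replicate 1 and anac090 replicate 3, a setting added after the data were seen, 1762 and 1888.

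The comparison of the libraries labelled anac082 with wild type asks the same for ANAC082, known as a factor in the response to disturbed ribosome assembly. Besides ANAC082 itself, 4 genes rose and 3 fell, all named after their values were seen. The cyclophilin gene CYP21-2 rose 10.9-fold (3.45 ± 0.11, adjusted p = 4.4e-08), and AT3G05170, listed at 0 in all 3 wild type libraries, was higher by 2.06 ± 0.13 (adjusted p = 3.0e-05). QQS, a gene of starch metabolism, rose 2.55-fold (1.35 ± 0.19, adjusted p = 0.0483) and AT3G29644 by 1.02 ± 0.12 (0.0197). HEI10, which acts in meiotic crossovers, fell by 2.38 on the log2 scale (SE 0.34, adjusted p = 0.0483), the retroelement SADHU3-2 by 1.66 (SE 0.22, 0.0390) and PSF1, a replication factor gene, by 1.21 (SE 0.17, 0.0483). With the block the calls of HEI10 (0.106), SADHU3-2 (0.110), PSF1 (0.0534) and QQS (0.147) were lost.

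No member of a fixed list passed limma's threshold in anac082, but 12 lists passed camera's, 10 higher and 2 lower (13 with the block). With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and fry gave 0 as well (1 unadjusted). The 17 ROS and stress genes had a median of 0.76 (camera adjusted p = 2.8e-09, and adjusted p = 0.376 with an estimated correlation; 4 rose adjusted over the list alone), for example ZAT12 at 0.95 ± 0.27 (adjusted p = 0.664). WRKY33 was at 0.87 ± 0.25 (0.664). The SA-responsive genes had a median of 0.84 (3.8e-05, and adjusted p = 0.473 with an estimated correlation; 3 adjusted over the list alone), with PR2 at 1.88 ± 0.56, PR5 at 1.85 ± 0.64 and PR1 at 1.89 ± 0.79. SA synthesis genes had a median of 0.71 (3.7e-05, and adjusted p = 0.505 with an estimated correlation; none adjusted over the list alone), with CBP60G at 1.00 ± 0.45. Their list mean lay -0.05 from wild type in anac082 replicate 1, the library near wild type on the first principal component, and 1.16 and 0.77 above it in replicates 2 and 3. For SA-responsive genes these were 0.19, 1.72 and 1.11. On that list the wild type libraries themselves lay at -0.32, 0.14 and 0.18 from their mean in replicates 1 to 3. Each anac082 library was thus above the wild type library of the same number, replicate 1 included. Protein folding genes had a median of 0.79 (2.9e-05, and adjusted p = 0.450 with an estimated correlation; none adjusted over the list alone), with the chaperone BIP3 at 1.48 ± 0.57. List means were 0.02, 1.35 and 1.23 above wild type in replicates 1 to 3. The mitochondrial list had a median of 0.33 (0.00222, and adjusted p = 0.475 with an estimated correlation; 1 adjusted over the list alone), with BCS1 at 1.2 ± 0.31. Senescence-associated genes had a median of 0.23 (0.00398, and adjusted p = 0.450 with an estimated correlation; 1 adjusted over the list alone), with SAG14 at 1.76 ± 0.45. NAC factors had 0.25 (6.8e-04, and adjusted p = 0.505 with an estimated correlation; none adjusted over the list alone), with NAC036 at 0.80 ± 0.27. List means were 0.12, 0.74 and 0.52 for senescence (call lost without replicate 2, adjusted p = 0.0615), 0.60, 0.89 and 0.68 for ROS and stress, 0.34, 0.60 and 0.33 for mitochondrial genes and 0.18, 0.37 and 0.40 for NAC factors.

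Jasmonate genes in anac082 had a median of 0.20 (camera adjusted p = 0.00168, and adjusted p = 0.505 with an estimated correlation; 1 rose adjusted over the list alone), with the repressor gene JAZ5 at 0.95 ± 0.21. Camalexin and indole glucosinolate genes had a median of 0.74 (0.00199, and adjusted p = 0.450 with an estimated correlation) and ribosome genes 0.17 (8.8e-04, and adjusted p = 0.505 with an estimated correlation), with NOP56 at 0.42 ± 0.21. Lower lists were chlorophyll synthesis (-0.28, 0.0054, and adjusted p = 0.450 with an estimated correlation) and aliphatic glucosinolates (-0.24, 0.0193, and adjusted p = 0.606 with an estimated correlation). The last had list means of -0.14, -0.64 and -0.02 in replicates 1 to 3, and its call was lost without replicate 2 (adjusted p = 0.511) or wild type replicate 3 (0.233). List means were 0.26, 1.00 and 0.84 for camalexin, 0.11, 0.19 and 0.20 for ribosome, -0.16, -0.27 and -0.32 for chlorophyll synthesis and 0.14, 0.12 and 0.38 for jasmonate genes. None of the camalexin, ribosome, chlorophyll synthesis and aliphatic lists had a member past the threshold adjusted over the list alone. Not past camera's threshold were ROS scavenging (0.02, adjusted p = 0.381), chlorophyll breakdown (0.03, 0.598), photosynthesis (-0.03, 0.363), ethylene (0.00, 0.703), abscisic acid (-0.02, 0.832), type-A response regulators (-0.16, 0.527), heat shock (-0.17, 0.527), anthocyanin (-0.14, 0.281) and the clock (-0.02 but mean 0.07, 0.883). Markers of guard cells (-0.15, 0.328), vasculature (-0.04 but mean 0.22 and a test upwards, 0.381; 1 adjusted over the list alone) and epidermis (-0.48, 0.107, block 0.0476) did not pass either. The clock index was 1.76 ± 0.93 against 2.55 ± 0.93 in wild type.

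In all, 5 genes rose and 3 fell in anac082, each at least 2-fold, with 1206 genes at an unadjusted p under 0.05 and 3145 genes (18.7%) separated, against 10% by chance. With the block 4 rose and 2 fell. The 4 calls in both fits are rises, so the 2 falls with the block are other genes than the 3 without it. The count of rises was 3 without wild type replicates 1, 2 or 3, anac017 replicate 2, anac082 replicates 1 or 2 or anac090 replicate 1, and that of falls was 0 in limma without wild type replicate 2, anac017 replicates 2 or 3, anac082 replicates 1 or 2 or anac090 replicates 1 or 2 and 1 without wild type replicates 1 or 3, anac017 replicate 1, anac082 replicate 3 or anac090 replicate 3. Weights per library gave 423 and 253, leaving out anac082 replicate 1 and anac090 replicate 3, added after the data were seen, gave 417 and 303, and rescaling by trimmed means or by medians of ratios gave 4 and 1, which moved the share of rises from 62.5% to 80%.

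The comparison of the libraries labelled anac090 with wild type asks the same for ANAC090. Among separated genes above the median mean value, the largest rise was that of the ATPase gene AT3G28510 (14.3-fold, 3.84 ± 0.93). PR1, a marker of the SA response, rose 12.1-fold (3.6 ± 0.79, adjusted p = 0.0357), SAG14 8.97-fold (3.17 ± 0.45, 0.0184) and the NPR1-interacting gene NIMIN-2 7.62-fold (2.93 ± 0.56, 0.0304). AT3G18250 rose 8.09-fold (3.02 ± 0.75), ZAT7 7.80-fold (2.96 ± 0.39), EGC2 7.72-fold (2.95 ± 0.66) and AT1G65690 6.75-fold (2.76 ± 0.62). Under the same limits, the largest falls were those of the jasmonate-responsive defensins PDF1.2 (-2.65 ± 0.64), PDF1.2B (-2.40 ± 0.50) and PDF1.2C (-2.39 ± 0.61), near-identical genes between which the split of reads is uncertain. LHCB2.4, an antenna protein of photosystem II, changed by -1.79 ± 0.48, and genes of the cell wall by -1.75 ± 0.33 (XTH7), -1.57 ± 0.35 (pectate lyase AT4G24780) and -1.48 ± 0.36 (the expansin EXPA11). AT1G13650 changed by -1.52 ± 0.33, and all 16 genes passed the threshold. The clock index was 1.46 ± 0.72 against 2.55 ± 0.93 in wild type.

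By list, 8 of 10 SA-responsive genes rose in anac090 (8 adjusted over the list alone), with a median of 2.00, among them GRXC9 (2.73 ± 0.39), WRKY38 (2.78 ± 0.50) and WRKY70 (1.84 ± 0.35). Camera gave adjusted p = 1.6e-07, and adjusted p = 0.450 with an estimated correlation. Their list mean lay 2.05, 1.27 and 3.17 above wild type in replicates 1, 2 and 3, the last being the library far out on the first principal component. Of 17 SA synthesis genes, 3 rose, the regulators SARD1 (1.99 ± 0.40) and CBP60G (2.2 ± 0.45) and the SA receptor gene NPR3 (0.86 ± 0.22), while 16 rose adjusted over the list alone and 9 with the block. The median was 1.39 (camera adjusted p = 6.6e-08, and adjusted p = 0.473 with an estimated correlation), and list means were 1.17, 0.59 and 2.53. ICS1, the SA synthesis enzyme, was at 1.39 ± 0.47 (adjusted p = 0.0768, block 0.0434). Of 17 ROS and stress genes 11 rose (13 adjusted over the list alone, 13 with the block), among them WRKY18 (2.38 ± 0.32), WRKY33 (1.32 ± 0.25) and the oxidase gene RBOHD (0.42 ± 0.10), at a median of 1.35. Camera gave adjusted p = 7.9e-09 (adjusted p = 0.376 with an estimated correlation), with list means of 1.19, 0.93 and 1.67. Of 14 mitochondrial genes 2 rose (4 adjusted over the list alone, 4 with the block), BCS1 (1.41 ± 0.31) and NDA2 (1.04 ± 0.26), at a median of 0.56. Camera gave 5.4e-04 (adjusted p = 0.450 with an estimated correlation), with list means of 0.61, 0.42 and 1.14. Of 12 senescence-associated genes 4 rose (7 adjusted over the list alone, 7 with the block), SAG14, SAG20 (0.64 ± 0.12), SAG21 (2.23 ± 0.46) and GLN1;1 (1.31 ± 0.32), at a median of 0.65. Camera gave 5.4e-04 (adjusted p = 0.450 with an estimated correlation), with list means of 0.78, 0.78 and 1.48. Of 23 NAC factors 7 rose (11 adjusted over the list alone, 10 with the block), among them NAC036 (1.82 ± 0.27), NAC016 (1.84 ± 0.29), ATAF2 (1.29 ± 0.28) and NAC061 (2.04 ± 0.45), at a median of 0.53. Camera gave 1.2e-05 (adjusted p = 0.505 with an estimated correlation), with list means of 0.69, 0.22 and 1.31. Over all tested genes, anac090 had only 12, 11 or 17 calls without wild type replicate 1, 2 or 3, and 3 with only these groups fitted. Most calls of single list members in this paragraph are thus lost in each of these settings.

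Of 6 chlorophyll synthesis genes 2 fell in anac090, AT1G44446, known as CAO (-0.52 ± 0.12), and CHLH (-0.60 ± 0.16). Adjusted over the list alone 5 were lower, 4 with the block, at a median of -0.53 (camera adjusted p = 0.00246, and adjusted p = 0.450 with an estimated correlation). Their list mean was -0.34, -0.33 and -0.82 in replicates 1 to 3. No photosynthesis gene of 27 passed, also adjusted over the list alone. With the block 3 passed, LHCB2.2 (-0.48 ± 0.14, adjusted p = 0.0548, block 0.0298), GAPB (-0.53 ± 0.15, 0.0563, block 0.0466) and RBCS3B (-0.54 ± 0.17, 0.0658, block 0.0466). The median was -0.15 (camera adjusted p = 0.0023, and adjusted p = 0.564 with an estimated correlation), with list means of -0.10, -0.10 and -0.43. Camalexin and indole glucosinolate genes rose in 3 of 6 cases (3 adjusted over the list alone), MYB51 (0.98 ± 0.17), CYP79B2 (1.67 ± 0.35) and PAD3 (2.16 ± 0.54). Their median was 1.53 (7.6e-04, and adjusted p = 0.450 with an estimated correlation), with list means of 1.14, 0.52 and 2.39. Of 10 aliphatic glucosinolate genes the regulator MYB29 fell (-1.12 ± 0.28; 9 adjusted over the list alone, 2 with the block), with a median of -0.65 (6.3e-04, and adjusted p = 0.505 with an estimated correlation) and list means of -0.45, -0.34 and -1.21. Of 7 protein folding genes the stress factor BZIP60 rose (0.81 ± 0.19; 1 adjusted over the list alone), with a median of 0.89 (0.00246, and adjusted p = 0.505 with an estimated correlation) and list means of 0.79, 0.32 and 1.59. Type-A response regulators had a median of -0.61 with none past the threshold (3 adjusted over the list alone; camera 0.0427, and adjusted p = 0.505 with an estimated correlation). Their list means were -0.19, -0.55 and -0.97, and the call was lost without replicate 2 (0.140) or 3 (0.0781) or wild type replicate 3 (0.124). ARR9 (-0.81 ± 0.22, adjusted p = 0.0508) passed with the block (0.0377). Ribosome genes had a median of 0.12 (0.0458, and adjusted p = 0.649 with an estimated correlation), with 0 past limma's threshold, also adjusted over the list alone, and 2 with the block. Their list means were 0.20, -0.07 and 0.35, and the call was lost without replicate 1 (0.138) or 3 (0.279), wild type replicates 1 (0.0743) or 2 (0.193) or anac082 replicate 2 (0.0548).

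In all, 13 lists passed camera's threshold in anac090, 9 higher and 4 lower (14 with the block), 6 passed fry, and 0 passed camera with an estimated correlation, where 2 had an unadjusted p under 0.05. Lists not past camera's threshold still held members that passed. Of 18 jasmonate genes OPR3 (0.70 ± 0.17), JAZ5 (1.19 ± 0.21) and JAZ7 (1.60 ± 0.36) rose and PDF1.2 and PDF1.2B fell (7 and 2 adjusted over the list alone, 5 and 2 with the block), with a median of 0.11 but a mean of -0.11 (camera adjusted p = 0.19). Of chlorophyll breakdown genes AT4G11910 rose (1.18 ± 0.27) and RCCR fell (-0.64 ± 0.15), at a median of 0.18 (0.434). Adjusted over the list alone 2 and 2 passed, and 2 and 2 with the block. Of ROS scavenging genes the catalase AT1G20620 rose (0.48 ± 0.12; 2 adjusted over the list alone, 2 with the block), with a median of -0.09 but a mean of 0.04 (0.527). The clock gene PRR9 fell (-0.47 ± 0.12; 1 adjusted over the list alone), at a list median of -0.16 (0.498, though fry gave adjusted p = 0.0352). With the block CCA1 (-0.69), LHY (-0.57) and RVE1 (-0.70) were lower and TOC1 (0.71) and ELF4 (0.71) higher. SWEET12 rose among the vascular markers (1.39 ± 0.36; 1 adjusted over the list alone, 2 with the block), with a median of 0.04 (0.574). The medians of ethylene (-0.02 but mean 0.08, 0.598; 1 adjusted over the list alone), abscisic acid (-0.08, 0.749), heat shock (0.24, 0.352), anthocyanin (-0.28, 0.354) and guard cell genes (-0.09, 0.774) came with no call. With the block 1 ethylene gene was higher and 1 lower, and 1 abscisic acid gene was lower. Epidermis markers had a median of -0.91 (0.0795, block 0.0363; 2 adjusted over the list alone, 2 with the block), with list means of -1.09, -0.11 and -1.55.

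**Figure D3:**
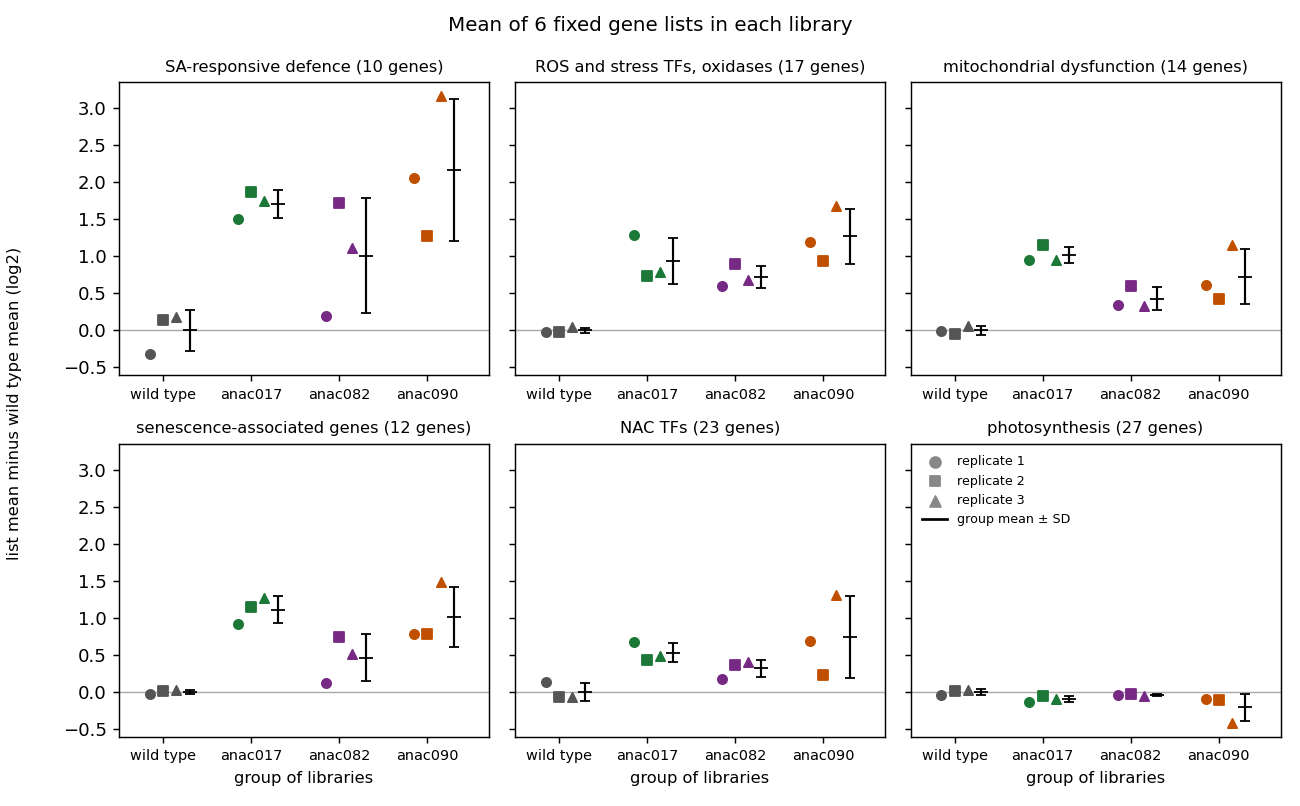
Mean of the tested genes of 6 fixed lists in each library, minus the wild type mean (log2), by group; marker shapes give replicate numbers and bars the group mean ± SD (n = 3). The SA-responsive list lies at 0.19 in anac082 replicate 1 and at 3.17 in anac090 replicate 3.

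In anac090 a total of 616 genes rose and 613 fell (1378 and 1691 with the block), 327 and 90 of them at least 2-fold, and 5314 genes (31.6%) were separated, against 10% by chance. These counts became 10 and 2 without wild type replicate 1, 9 and 2 without 2, 13 and 4 without 3, 221 and 156 without anac017 replicate 1, 136 and 70 without 2, 110 and 58 without 3, 196 and 106 without anac082 replicate 2, 85 and 44 without 3, 182 and 172 without anac090 replicate 1, 2320 and 2694 without 2 and 147 and 101 without 3. With only these groups fitted 2 rose and 1 fell, with weights per library 3552 and 4004, at a threshold of 0.01 10 and 1, with no filter 248 and 213, without anac082 replicate 1 and anac090 replicate 3, added after the data were seen, 485 and 400, and the share of rises moved from 50.1% to 63.3% with trimmed means (691 and 400) and 62.4% with medians of ratios (660 and 397). The shared spread pools 4 groups that are not alike. Over the tested genes, the mean absolute difference between libraries was 0.29, 0.37 and 0.53 log2 units in anac090, against 0.20 to 0.22 in wild type. It was 0.19 to 0.22 in anac017 and 0.16 to 0.28 in anac082. The p-values of anac090 thus rest in part on the smaller spread of other groups and do not measure its own spread alone.

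The mutants were also compared with each other, to ask whether they differ. The wild type libraries enter these tests only through the filter and the shared spread. Against anac082, the linker histone gene HIS1-3, known from drought responses, was 4.88-fold higher in anac017 (2.29 ± 0.23, adjusted p = 0.00132). AT4G32240 (1.41 ± 0.14), AT1G45165 (1.34 ± 0.23), the transposable element gene AT2G13975 (1.27 ± 0.10) and the RNA gene AT1G69252 (1.19 ± 0.15) were higher too. ANAC082 was lower in anac017 (-3.76 ± 0.11, adjusted p = 3.7e-08), as were AT4G18280 (-1.04 ± 0.19), AT5G63500 (-1.0 ± 0.18), AT2G23120 (-0.91 ± 0.10) and AT4G04410 (-0.87 ± 0.17). The mitochondrial list was higher in anac017 by a median of 0.54 (camera adjusted p = 1.5e-05, and adjusted p = 0.693 with an estimated correlation), with 3 of 14 genes called (6 adjusted over the list alone): AT2G21640 (1.94), UGT74E2 (1.39) and SOT12 (0.65). With the block 1 clock gene was lower. SA synthesis (0.39, 0.00474, and adjusted p = 0.827 with an estimated correlation) was higher too. So were the SA-responsive (0.76, 0.00571), senescence-associated (0.55, 0.00152), anthocyanin (0.59, 0.00846) and camalexin (0.72, 0.0146) lists, while type-A response regulators were lower (-0.60, 0.00162), each at adjusted p = 0.693 with an estimated correlation. Aliphatic glucosinolates were lower (-0.38, 0.0135, and adjusted p = 0.799 with an estimated correlation). In all 130 genes were higher and 20 lower in anac017 than in anac082 (200 and 55 with the block). The total of 150 became 114, 117 and 120 without wild type replicates 1, 2 and 3, 35, 42 and 40 without anac017 replicates 1, 2 and 3, 98, 50 and 45 without anac082 replicates 1, 2 and 3 and 281 without anac090 replicate 3, and was 940 with weights per library, 29 at 2-fold and 48 at a threshold of 0.01.

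Against anac090 and among separated genes above the median mean value, the genes with the largest differences upwards in anac017 were AT1G69252 (1.61 ± 0.15), AT2G13975 (1.56 ± 0.10), AT4G32240 (1.54 ± 0.14), AT1G45165 (1.45 ± 0.23) and the RNA-binding protein gene AT4G09040 (1.40 ± 0.23). Lower in anac017 were AT1G24530 (-1.07 ± 0.19), AT2G23120 (-0.92 ± 0.10), AT2G34655 (-0.80 ± 0.15), the calmodulin gene AT2G41110 (-0.75 ± 0.16) and AT4G23880 (-0.72 ± 0.14). AT2G21640 of the mitochondrial list was higher by 2.21, and the list did not pass (0.03, camera adjusted p = 0.0546; 6 adjusted over the list alone, 2 with the block). The ROS and stress list was lower in anac017 (-0.39, 0.00846) and the anthocyanin list higher (0.69, 0.00474), both at adjusted p = 0.693 with an estimated correlation. NAC factors (-0.18, 0.0346, and adjusted p = 0.862 with an estimated correlation) were lower. Photosynthesis genes (0.10, 0.0229, and adjusted p = 0.852 with an estimated correlation) were higher, and chlorophyll synthesis passed with the block only (0.21, 0.0632, block 0.0271; 1 gene with the block). In all 220 genes were higher and 29 lower in anac017 (319 and 66 with the block). The total of 249 became 186, 193 and 222 without wild type replicates 1, 2 and 3, 80, 92 and 103 without anac017 replicates 1, 2 and 3, and was 13 with only these groups fitted, 3868 with weights per library, 53 at 2-fold and 77 at a threshold of 0.01.

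Between anac082 and anac090, ANAC082 was 21.9-fold higher in anac082 (4.45 ± 0.11, adjusted p = 6.2e-09) and QQS 3.78-fold (1.92 ± 0.19, adjusted p = 0.00654), and 0 genes were lower in limma, with 886 lower at an unadjusted p under 0.05. A total of 2116 genes (12.6%) were separated, against 10% by chance. By camera, SA-responsive genes (-1.40, adjusted p = 1.5e-05), SA synthesis (-0.64, 1.5e-05), ROS and stress genes (-0.44, 1.7e-04), NAC factors (-0.28, 1.8e-04), senescence-associated genes (-0.49, 0.00395), the mitochondrial list (-0.22, 0.0207), camalexin (-0.63, 0.016) and heat shock genes (-0.32, 0.0487) were lower in anac082. Photosynthesis (0.14, 0.00152), aliphatic glucosinolates (0.40, 0.00395), type-A response regulators (0.38, 0.0346) and chlorophyll synthesis (0.26, 0.0406) were higher, and each of the 12 lists had adjusted p = 0.693 with an estimated correlation. Adjusted over the list alone, 7 of 10 SA-responsive genes, 2 ROS and stress genes, 2 NAC factors and 1 gene each of the senescence, camalexin and chlorophyll breakdown lists were lower. Higher on that count were 2 jasmonate genes, 1 type-A response regulator and 1 chlorophyll breakdown gene. The total of 2 became 1 without anac082 replicates 1 or 2, 4 without anac090 replicate 1 and 17 without anac090 replicate 2. It was 3801 with weights per library, 4 with no filter and 1 without anac082 replicate 1 and anac090 replicate 3.

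A small set of 5 genes was called in all 3 comparisons with wild type. CYP21-2 (AT3G55920, chromosome 3, 20743443 to 20745083) was at 0.15 ± 0.13 in wild type and 3.66 ± 0.11 in the mutant libraries (n = 9), with changes of 3.57, 3.45 and 3.52 in anac017, anac082 and anac090. AT3G05170 (chromosome 3, 1466573 to 1468400) was listed at 0 in wild type and stood at 2.13 ± 0.15 in the mutants, and AT3G29644 (chromosome 3, 11499199 to 11501366) at 2.13 ± 0.16 and 3.21 ± 0.13. HEI10 (AT1G53490, chromosome 1, 19963267 to 19966952) was lower, at 2.98 ± 0.87 in wild type and 0.75 ± 0.18 in the mutants, as was SADHU3-2 (AT3G42658, chromosome 3, 14749400 to 14750294), at 2.90 ± 0.14 and 0.59 ± 0.55. The wild type libraries of HEI10 lay at 2.19 to 3.92 and the mutant libraries at 0.55 to 1.01. SADHU3-2 lay at 0.10 to 1.59 in the mutant libraries, highest in anac082, with changes of -2.62, -1.66 and -2.65. With the block 5 genes were also called in all 3 comparisons, but only 3 of them are among these 5, as HEI10 and SADHU3-2 were lost in anac082. Without any 1 library CYP21-2 and AT3G05170 stayed. In anac082 the call of AT3G29644 was lost without any 1 of the wild type libraries, anac017 replicate 2, anac082 replicates 1 or 2 or anac090 replicate 1. That of HEI10 was lost there without any 1 library but wild type replicates 1 and 3, and that of SADHU3-2 without any but anac017 replicate 1 and anac082 replicate 3. HEI10 also lost its call in anac017 without wild type replicate 2 or any 1 of the anac017 libraries, and in anac090 without wild type replicate 2.

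**Figure D4:**
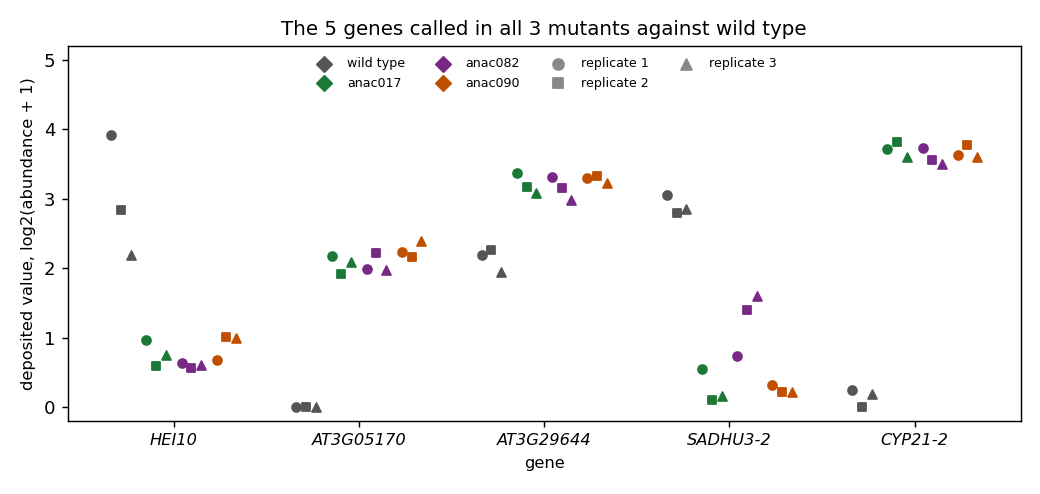
Deposited log2(abundance + 1) in each library of the 5 genes called in all 3 mutants; colours give the groups and marker shapes the replicate numbers. AT3G05170 lies at 0 in wild type and at 1.91 to 2.39 in the 9 mutant libraries.

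The overlap of the comparisons with wild type was counted to see whether the mutants share changes. In anac017 and anac090, 103 genes were called in the same direction (54 higher and 49 lower; 586 with the block) and 3 in opposite ones, where independent lists would give 9.08 and 3.75. In anac017 and anac082 there were 6 (4 higher and 2 lower) and 1 opposite, against 0.0737 and 0.0184, and in anac082 and anac090 5 (3 and 2) and 0 opposite, against 0.183 and 0.109. These 5 are the genes called in all 3 comparisons, and the 6 are the same genes and ANAC082, the gene targeted in anac082. The 5 may differ between the wild type line and the mutant lines for reasons apart from the NAC genes. In 100 simulated sets of unchanged groups against a shared simulated wild type, drawn from the deviations of the wild type libraries, the mean was 0. These groups hold no change, so few calls can arise there. The 0 thus does not show how many shared calls come from the shared wild type. The log2 changes correlated across genes, which are not independent replicates, at 0.76 (anac017 and anac082), 0.79 (anac017 and anac090) and 0.81 (anac082 and anac090), where the simulated sets had a mean of 0.32, and 8, 6 and 5 of the 100 sets reached these values. Their highest value of 1 is a product of how they were drawn. The covariances were 0.0899, 0.168 and 0.112 against a simulated mean of 0.0147 and a highest simulated value of 0.0775, and the shares of genes with the same sign 76.6%, 78.2% and 79.9% against 62.2%. Part of the excess may come from the shared wild type libraries, which are too few to split. The 103 shared genes became 9, 6 and 9 without wild type replicates 1, 2 and 3, 7, 23 and 8 without anac017 replicates 1, 2 and 3, 44 and 20 without anac082 replicates 2 and 3 and 37, 1138 and 193 without anac090 replicates 1, 2 and 3. The 6 became 3 without wild type replicate 2, anac017 replicate 2, anac082 replicates 1 or 2 or anac090 replicate 1, and the 5 became 3 without wild type replicates 1 or 3, anac017 replicate 3 or anac090 replicate 3 and 2 without wild type replicate 2, anac017 replicate 2, anac082 replicates 1 or 2 or anac090 replicate 1. Without anac082 replicate 1 and anac090 replicate 3, the shared counts were 604, 705 and 357 for anac017 and anac082, anac017 and anac090, and anac082 and anac090.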

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

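The tests of swapped libraries and of exchanged labels, of the defence axis and of genetic background behind the shared genes, of the replicate number and of the time of harvest for anac082 replicate 1 were chosen after the results were seen. Entries of the table without a gene identifier are used in no comparison of the report, and 41 of them passed the filter. Against wild type, 5 of them were higher in anac017: at chromosome 1, 7892878, by 0.53 (adjusted p = 0.0184), at chromosome 3, 9103087, by 1.42 (9.5e-04), 9570418 by 1.22 (0.0281) and 22575591 by 0.62 (0.0306), and at chromosome 4, 5770770, by 1.18 (0.0143). In anac090 the entry at chromosome 1, 26724925, differed by -0.90 (0.0371) and that at chromosome 2, 15849271, by 1.34 (0.0280).

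The transcript of ANAC082 was 28.0-fold higher in the libraries labelled anac082. Swaps of single libraries are argued against by the gap of 3.56 log2 units between the lowest of these libraries and the highest other one. Reads of the closest paralog are argued against by NAC103, which changed by -0.029 (SE 0.07) and whose highest value in any library was 0.35. Transcription that spreads over the region is argued against by the 5 tested genes within 10 kb, with a median change of -0.20, and by the nearest, VPS9B at -0.24 ± 0.15, though the farther SAL4 and T5E8_100 were at 1.04 ± 0.47 and 0.40 ± 0.25. What stays open is an exchange of labels between whole groups or a line with another insertion than its label says, which leave the same gap (ANAC017 changed by 0.0248 in anac082), and transcription of the gene itself that starts in or near the insertion, which was not tested.

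The 5 genes called in all 3 mutants may differ between the wild type line and the mutant lines for reasons apart from the NAC genes. The defence axis that parts the libraries is argued against for 3 of them by libraries left out of the calls: anac082 replicate 1 lay at a median of 0.976 of the way from wild type to the other mutant libraries for AT3G05170 and CYP21-2 (0.0671 for the SA-responsive list), and anac090 replicate 3 at 1.01 for these and AT3G29644 (0.982 to 1.141, against 2.44). For the other 2, HEI10 and SADHU3-2, it stays open, since both libraries helped to call them. A difference of genetic background stays open: 0 pairs of the 5 lie within 1 Mb of each other, 4 of 5 lie on 1 chromosome, as in 4.28% of 10000 random draws, and their median SD over the 9 mutant libraries was 0.151 against 0.207 for all tested genes. A biological effect common to all 3 mutants also stays open, as untested.

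The libraries of 1 mutant differed along the axis of defence genes. The replicate number as a shared batch stays open: on the mean of the SA-responsive list, same-numbered libraries deviated together in 15 of 18 pairs (exact permutation p = 0.375, one-sided, 216 arrangements), but replicate 2 lay 0.71 above its group mean in anac082 and -0.89 from it in anac090. The time of harvest within the day is argued against only for the gap between anac090 replicates 3 and 2, whose clock index differed by 0.0309, and stays open for anac082 replicate 1, whose index lay -1.61 from replicates 2 and 3 (-1.25 to -1.59 in the other groups). A second index of other clock-linked genes, used further below, was less alike, at -2.55 in anac090 replicate 3 and -2.14 in anac090 replicate 2. Other tissue in the sample stays open, with median differences of -0.238 for vascular markers, -0.08 for guard cell markers and -1.07 for epidermis markers between anac090 replicates 3 and 2. A biological difference between leaves of 1 line stays open, as untested.

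With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. Of the splits of the 6 libraries, the real one called 351 genes in anac017 against wild type, 8 in anac082 and 1229 in anac090, with at most 0 in any other split (1 split each with as many, the real one). Between mutants the real splits called 150, 249 and 2 genes, and the highest others 0, 1 and 0. In the other splits each group mixes libraries of both lines, so a difference between the lines adds to the shared spread and lowers the calls. Their low gene counts are thus no measure of what chance gives. For lists past camera's threshold, the real split gave 10 in anac017 and another split gave 13, so that 2 splits gave as many. The real split gave 12 in anac082 and 13 in anac090, and the highest others gave 10 and 12. The other splits that part each replicate pair gave 9, 7 and 7 lists in anac017, 7, 4 and 10 in anac082 and 4, 11 and 11 in anac090, and the split with 13 parts 1 pair only. Between mutants, with lists adjusted within each comparison alone, the real splits gave 8 lists (anac017 and anac082), 2 (anac017 and anac090) and 12 (anac082 and anac090). Other splits of the same libraries gave up to 12, 11 and 13, so these list counts do not set the real grouping apart.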

How the results depend on the processing

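Leaving out a library of a group not compared, and leaving out anac082 replicate 1 and anac090 replicate 3 together, were chosen after the data were seen. For 216 values of named genes, 5170 alternatives gave 4144 values on the same side of the threshold, 741 that lost the call, 285 that gained it and 0 in the other direction. For 72 results of lists, 1863 alternatives gave 1757 on the same side, 78 lost, 28 gained and 0 reversed. Of these, 1719 kept camera with the preset correlation and gave 1676 on the same side, 17 lost and 26 gained. Most losses thus came with the estimated correlation or fry, and with the estimated correlation every list that had passed was lost. The cause was not tested for the values below, except that leaving out a library of a group not compared acts only through the shared spread. Depth is unknown, so what it limits cannot be given. Tests of counts with whole reads were not run, because whole reads could not be recovered.

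Leaving out 1 library gave 45 to 1410 rises and 3 to 1547 falls in anac017, 3 to 5 and 0 to 1 in anac082 and 9 to 2320 and 2 to 2694 in anac090. Between mutants it gave 35 to 281 genes (anac017 and anac082), 80 to 267 (anac017 and anac090) and 1 to 17 (anac082 and anac090), and shared genes of 3 to 5, 6 to 1138 and 2 to 5 in the same order. The change of ANAC017 in anac017 was 0.81 to 0.91 (log2). Lists past the threshold numbered 10 to 12, 10 to 13 and 12 to 13.

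A pseudocount of 0.1 or of 10 gave 1 fall in anac082. No filter gave 1 fall in anac082, 248 rises and 213 falls in anac090, 4 genes between anac082 and anac090 and 54 shared by anac017 and anac090. A minimum mean of 5 gave 3 rises and 0 falls in anac082 and shared counts of 3 (anac017 and anac082) and 2 (anac082 and anac090). Trimmed means gave 1 fall in anac082 and 400 in anac090, and medians of ratios 1 and 397. Weights per library gave 2191 and 2394 in anac017, 423 and 253 in anac082, 3552 and 4004 in anac090, 940, 3868 and 3801 between mutants and 543, 3376 and 614 shared. Fitting only the groups compared gave 1731 and 1881 in anac017, 0 falls in anac082, 2 and 1 in anac090, 13 between anac017 and anac090 and 3, 3 and 2 shared. The replicate block gave 691 and 513 in anac017, 1378 and 1691 in anac090, 255 and 385 genes in anac017 against anac082 and anac090, 586 shared by anac017 and anac090 and 3 genes between anac082 and anac090. In that last comparison the numbers do not pair the libraries (correlations of deviations 0.50, -0.31 and 0.42). Beyond the values and counts per list in the report, the block changed no other call of a list or of a named gene. A minimum of 2-fold gave 74 and 28, 327 and 90, 29, 53 and 40 shared by anac017 and anac090. A threshold of 0.01 gave 43 and 3, 3 and 0, 10 and 1, 48, 77 and 3, 7 and 2 shared. Camera with an estimated correlation gave 0 lists in each comparison with wild type (3, 1 and 2 at an unadjusted p under 0.05, smallest adjusted p 0.376), and fry 5, 0 and 6 (9, 1 and 12 unadjusted). Without anac082 replicate 1 and anac090 replicate 3 there were 1762 and 1888 in anac017, 417 and 303 in anac082, 485 and 400 in anac090, 1 gene between anac082 and anac090 and 604, 705 and 357 shared.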

Other observations

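The test of a time-of-day difference behind the called genes against the main axis of the libraries was chosen after its result was seen. The gene families and both clock indexes were chosen after the data were seen. Some families, such as SAUR genes and defensins, hold genes already named above for large changes. The p-values of the families are thus descriptive and do not test a choice made beforehand. WRKY factors, regulators of defence, rose in anac090 in 15 of 50 tested cases, with a median of 0.62 (camera adjusted p = 3.3e-08 over 14 families and 3 comparisons, and adjusted p = 0.386 with an estimated correlation), among them WRKY51 (3.09), WRKY18 (2.38) and WRKY41 (1.85). Most of these 15, such as WRKY18, are also members of the fixed ROS and stress or SA-responsive lists. The WRKY result is thus not separate from those lists. Calmodulin-like genes, which read calcium signals, rose in 12 of 32 cases (0.81, 6.3e-08, and adjusted p = 0.208 with an estimated correlation), with CML41 at 2.56. Wall-associated kinases rose in 4 of 11 cases (0.51, 9.8e-06, and adjusted p = 0.208 with an estimated correlation), with WAK3 at 2.65. Cysteine-rich receptor-like kinases rose in 4 and fell in 1 of 25 cases (0.62, 3.0e-05, and adjusted p = 0.386 with an estimated correlation). These 4 families also passed camera in anac017 (medians of 0.33, 0.18, 0.29 and 0.22 in the same order, adjusted p = 2.9e-04, 0.0125, 8.0e-04 and 0.0357) and in anac082 (0.17, 0.24, 0.14 and 0.43, adjusted p = 4.7e-04, 4.7e-04, 0.0159 and 0.00433). Only the wall-associated kinase WAKL22 in anac017 (0.52) was called among them there, and with an estimated correlation adjusted p was 0.386 to 0.561. Defensins, glutathione S-transferases, ubiquitin ligases with a U-box or RING domain and cytochromes P450 passed camera in no comparison (adjusted p = 0.0712 to 0.901).

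Of 42 SAUR genes, which respond to auxin, 5 fell in anac017 (median -1.07, camera adjusted p = 8.6e-07, and adjusted p = 0.386 with an estimated correlation), among them SAUR67 (-1.80). In anac090 7 fell and SAUR9 rose (2.01), with a median of -0.58 (0.0065, and adjusted p = 0.516 with an estimated correlation). Expansins, which loosen cell walls, had medians of -0.65 in anac017 (0.00256; 1 of 16 fell) and -0.68 in anac090 (0.00341; 2 fell), and tubulins -0.47 (4.7e-04; 0 of 14) and -0.45 (0.00155; 1 fell), all at adjusted p = 0.496 with an estimated correlation. Aquaporins had medians of -0.31 (0.0453) and -0.35 (0.0433), with 0 of 21 past limma's threshold in either, both at adjusted p = 0.673 with an estimated correlation. Arabinogalactan protein genes had a median of -0.60 in anac017 (0.014, and adjusted p = 0.624 with an estimated correlation; 0 of 30 in limma) but did not pass in anac090 (-0.45, 0.489; 1 rose). In anac082 no member was called, and SAUR genes (-0.24, adjusted p = 0.0125), expansins (-0.36, 0.0108) and tubulins (-0.22, 0.00256) passed camera, at adjusted p = 0.545, 0.526 and 0.516 with an estimated correlation, while aquaporins (-0.07, 0.519), arabinogalactan (-0.11, 0.537) and xyloglucan genes (-0.07, 0.278) did not. Xyloglucan endotransglucosylases/hydrolases passed in neither anac017 nor anac090, with medians of -0.35 (0.251; 0 of 19 in limma) and -0.02 (0.616; 2 fell).

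The clock index was higher in wild type than in the mean of the mutants by 0.924, 1.11 and 0.978 in replicates 1 to 3, and a candidate explanation is that wild type leaves were taken at another time of the day. A second index of other clock-linked genes, with 7 tested, was higher in wild type by 0.681, 0.735 and 1.33, a mean of 0.914, which is in line with this. A change of the clock in the mutants would give the same and stays open. Whether a time-of-day difference lies behind the called genes was tested with the change from replicates 2 and 3 to replicate 1 in the other mutants: 31.8% of the genes called in anac090 and 41.6% of those called in anac017 moved that way. Over all tested genes the shares were 36.9% for anac090 and 39.0% for anac017, so the called genes differed little from the rest. The shares of called genes met the bound set before against the explanation, but that contrast also follows the main axis of the libraries (correlation across genes with its loadings -0.53 and -0.61, a check added after the shares were seen), so it cannot be told apart from the defence axis.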
